A study of Mus musculus with 2 samples.

How the data were processed

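The series compared the transcriptomes of alveolar macrophages, the resident macrophages of the lung airspaces, from adult C57BL6 mice. Per the labels' protocols, lungs of littermates were digested with collagenase, and cells that excluded the dye DAPI and carried Siglec-F and CD11c were sorted as alveolar macrophages. The labels describe the wild type sample as carrying floxed Pikfyve alleles and the knockout sample as carrying the same alleles with LysM-Cre, a Cre recombinase driven from the lysozyme 2 locus of myeloid cells. Per the labels' protocols, total RNA was purified with a commercial kit, cDNA was amplified from 10 ng of it, labelled with biotin and hybridised to Affymetrix arrays. There was 1 array for each genotype, and the labels do not say how many mice gave the RNA of each array.

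The deposited table holds log2 values for 41345 rows (probe sets) on 2 arrays. The authors processed the arrays with RMA, per the submitters' processing notes; RMA corrects background, normalises the arrays to one distribution and summarises the probes of a row. Its version, the array annotation and the genome build are not given in the sources used here. The log base is taken from the method and from the range of the values, which ran from 0.77 to 13.86 in the wild type array and from 0.83 to 13.78 in the knockout array. The array medians were 5.17 and 5.10, and the sorted values of the arrays differed by at most 0.11. In 1022 rows, 2.47% of all, both arrays hold an identical value, which leaves 197 of the genes analysed with a difference of exactly 0. No scanner files or probe-level values were used here.

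Rows were named through a table of the platform's gene annotation. Of the rows, 23521 have 1 gene symbol, 1814 have several and 16010 are not listed. Only rows with 1 symbol were named, and their rows were averaged for the 1082 genes with more than 1 row, which gave 22180 genes. For 23328 of those rows the Entrez identifier was found in a RefSeq gene table (assembly GRCm38.p6), and no symbol differed from it. Genes entered the comparison when the mean of both arrays reached the median of all rows, 5.13, which left 12516 genes. The 1429 olfactory, vomeronasal and taste receptor genes, most of them silent outside sensory tissues, served as a measure of background. Their 95th percentile was 5.37 in the wild type array and 5.31 in the knockout array. Where a fold is given for a gene below that level on 1 array, it is written "at least" and measured from that level.

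With 1 array per genotype there are no residual degrees of freedom, so no test, p-value or standard error of a difference was computed. Differences are knockout minus wild type on the log2 scale, and folds are their powers of 2. Array signals compress large folds, so folds are estimates on this platform's scale. As a description of scatter, the local spread is 1.4826 times the median absolute deviation of differences in 20 bins of mean level. It ranged from 0.20 to 0.33, and holds both noise and any real differences. The number of arrays limits the precision, and signal over background is the only depth the values show.

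Before the data were examined, 44 gene lists, the thresholds and the rule for naming genes were fixed. The rule took Pikfyve, the 15 genes with the largest positive and the 15 with the largest negative difference (leaving out predicted genes, small RNAs and immunoglobulin or T cell receptor segments), and up to 4 members of each list with the largest absolute difference. Other list members named below were chosen after their values were seen. Each list was described by its members at least 2-fold and at least 1.5-fold apart and by its median. The median was ranked among 10000 random lists of the same size drawn from the genes that passed the filter and matched on mean level in the 20 bins. This percentile describes these 2 arrays and is not a test across animals. By chance 2.2 of 44 independent lists would lie outside the central 95% of random lists. The procedure was tested on simulated data for this comparison of 12516 genes. All 200 genes shifted by 2 log2 units were recovered (100.0%), with 0 unchanged genes called. The simulated differences of unchanged genes were limited to less than 2-fold, so this outcome was fixed in advance and checks only the code. Of 100 lists of 20 unchanged genes, 96 lay inside the central 95%, and all 100 lists shifted by 0.5 lay outside it. Those lists were drawn at random, so they do not stand for lists of genes that vary together. Shifts smaller than 0.5 were not simulated, though most list medians found outside the central 95% were smaller than that.

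The alternatives were other filters on low values, median centring, quantile normalisation and loess centring (span 0.3) between the arrays, an offset of 32 on the linear scale, the row with the highest mean for each gene, folds of 1.5 and 3, a threshold of 3 local spreads, and list means. A count without predicted genes, small RNAs and receptor segments was added after the data were seen. Leaving out a replicate was not possible. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.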

Results

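Sorted alveolar macrophages were profiled on Affymetrix microarrays to ask how loss of PIKfyve, the lipid kinase that makes phosphatidylinositol 3,5-bisphosphate on endosomes and lysosomes, alters their gene expression. There was 1 array labelled wild type and 1 labelled knockout, so the values below have no replicate error and no difference between genotypes was tested. Across the 12516 genes analysed the arrays correlated with Pearson's r = 0.978, a correlation across genes, which are not independent replicates, and 92.9% of genes differed by less than 1.5-fold. The median difference was -0.06 in the lowest decile of genes by level and 0.13 in the highest decile, so list medians are set beside random lists of matched level.

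Pikfyve was not lower in the array labelled knockout. Its row read 5.68 in the array labelled wild type and 5.95 in the array labelled knockout, a difference of 0.27 against a local spread of 0.26. Both values lay in the upper tail of the receptor genes that mark background, above 96.3% of them on the wild type array and 98.2% on the knockout array. Where its probes lie relative to the deleted part of the gene is not given in the sources used here, so the row does not check the labels. The groups are therefore called the array labelled wild type and the array labelled knockout throughout. The Y-linked Eif2s3y read 9.49 and 9.60, and Xist, the X-inactivation RNA, read 3.57 and 3.87, below the background level on both arrays. The other Y-linked genes that passed the filter, Uty and Kdm5d, differed by -0.24 and 0.03, and the sex-linked list had a median of 0.03.

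Genes of lipid-associated macrophages and of cholesterol synthesis were higher in the array labelled knockout, with list medians of 0.53 and 0.39. Immediate early genes and monocyte genes were lower, with list medians of -0.60 and -0.52, and so were the cytokine genes Tnf, Cxcl2 and Ccl2. The cytokine and chemokine list they belong to had a median of -0.05, inside the range of random lists, with 16 of 29 members lower and 12 higher. Marker lists of alveolar type 1 and airway epithelium, of T and NK cells and of interstitial or monocyte-derived macrophages were also higher. Their medians were 0.38, 0.23 and 0.30, though Epcam, of the epithelium list, was lower. Genes of alveolar macrophage identity had a median of -0.07, below the range of random lists, with 18 of 31 lower. Their mean was 0.01, inside the range of means of random lists.

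Across all genes, 116 were at least 2-fold higher and 42 at least 2-fold lower in the array labelled knockout, which is 0.93% and 0.34% of the genes analysed. Of these, 14 and 12 were predicted genes, small RNAs or receptor segments, and 14 and 8 lay at background on 1 array and are under 2-fold when measured from that level. For comparison, 1 of the 92 receptor genes that passed the same filter differed by 2-fold, a share close to the 1.26% of the genes analysed. So did 52 (3.64%) of all 1429 receptor genes, most of them below the filter. A threshold of 3-fold left 37 higher and 4 lower genes.

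**Figure D1:**
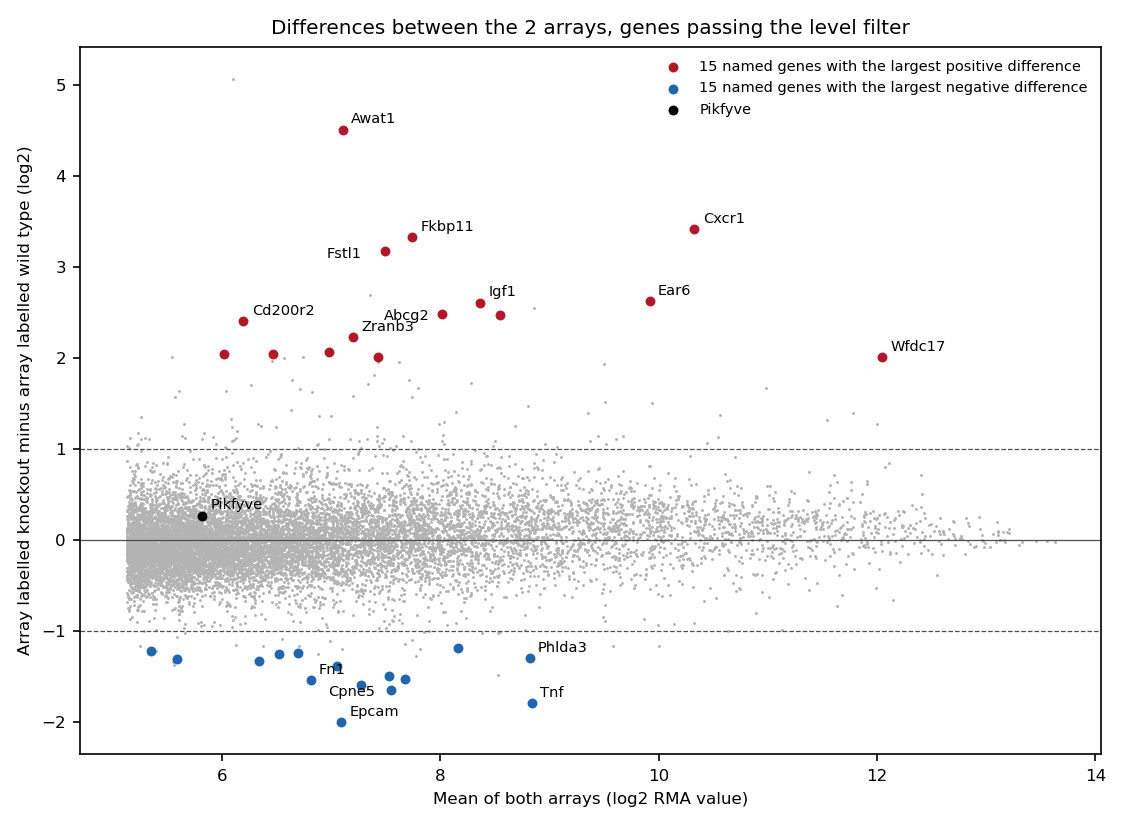
Difference between the arrays (labelled knockout minus labelled wild type, log2) against the mean of both arrays (log2 RMA value) for the 12516 genes that passed the filter; each point is a gene, dashed lines mark 2-fold, and colours mark the named genes. Epcam lies at -1.99 and Pikfyve at 0.27. Awat1 and the unlabelled grey point above it, the immunoglobulin segment Igkv8-30, were at background in the array labelled wild type. Their heights (4.50 and 5.06) are therefore not measured differences and stand for at least 15.9-fold and 9.57-fold. Other genes at background on 1 array are also plotted as read. Among the coloured points these are Cd200r2 and Gng8 (array labelled wild type) and Adgrl3 and Ascl3 (array labelled knockout).

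Among the 15 named genes with the largest positive differences, Awat1, an acyl-CoA wax alcohol acyltransferase, read 4.85 in the array labelled wild type, within background, and 9.36 in the array labelled knockout, at least 15.9-fold higher. The chemokine receptor gene Cxcr1 read 8.62 and 12.03, a 10.6-fold difference; it and Fn1 lie among the 100 measured genes next to Pikfyve. Fkbp11, a peptidyl-prolyl isomerase of the secretory pathway, was 10.0-fold higher (6.08 and 9.40). The secreted glycoprotein gene Fstl1 read 5.91 and 9.08, a difference of 3.17, and Igf1, insulin-like growth factor 1, was 6.10-fold higher (7.06 and 9.67). The ribonuclease gene Ear6 was 6.17-fold higher (8.60 and 11.23), and its family members are similar enough in sequence that probes can be shared. The efflux transporter gene Abcg2 was 5.58-fold higher (6.77 and 9.25). Bpifa1, a secreted protein of airway epithelium, was 5.53-fold higher. Cd200r2, of the CD200 receptor family, was at least 4.09-fold higher, and Gng8, a G protein gamma subunit, at least 3.19-fold higher. Zranb3 was 4.70-fold, Eci3 4.19-fold, Csta2 4.11-fold, Mamdc2 4.04-fold and Wfdc17 4.03-fold higher.

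The largest negative differences included an adhesion molecule, cytokines and matrix. Epcam, an epithelial adhesion molecule, was 3.98-fold lower in the array labelled knockout (8.09 and 6.09). Tnf, the inflammatory cytokine, was 3.46-fold lower (9.73 and 7.94). The membrane-binding protein gene Cpne5 was 3.12-fold lower, the chemokine gene Cxcl14 3.02-fold lower and the fibronectin gene Fn1 2.90-fold lower. Paip1, which acts in translation initiation, and Ube2v2, a ubiquitin-conjugating enzyme variant, were 2.87-fold and 2.82-fold lower. Gpr33 was 2.60-fold, Ms4a4c 2.51-fold, Phlda3 2.45-fold and Ikzf1, a lymphoid and myeloid transcription factor, 2.37-fold lower. Tnfsf13b, which encodes the B cell survival factor BAFF, was 2.35-fold lower, and the neutrophil chemokine gene Cxcl3 was 2.27-fold lower. Adgrl3 and Ascl3 reached background in the array labelled knockout and were at least 1.90-fold and 1.57-fold lower. As read, not measured from the background level, the 2 rows of Adgrl3 differed by -1.09 and -1.53.

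**Figure D2:**
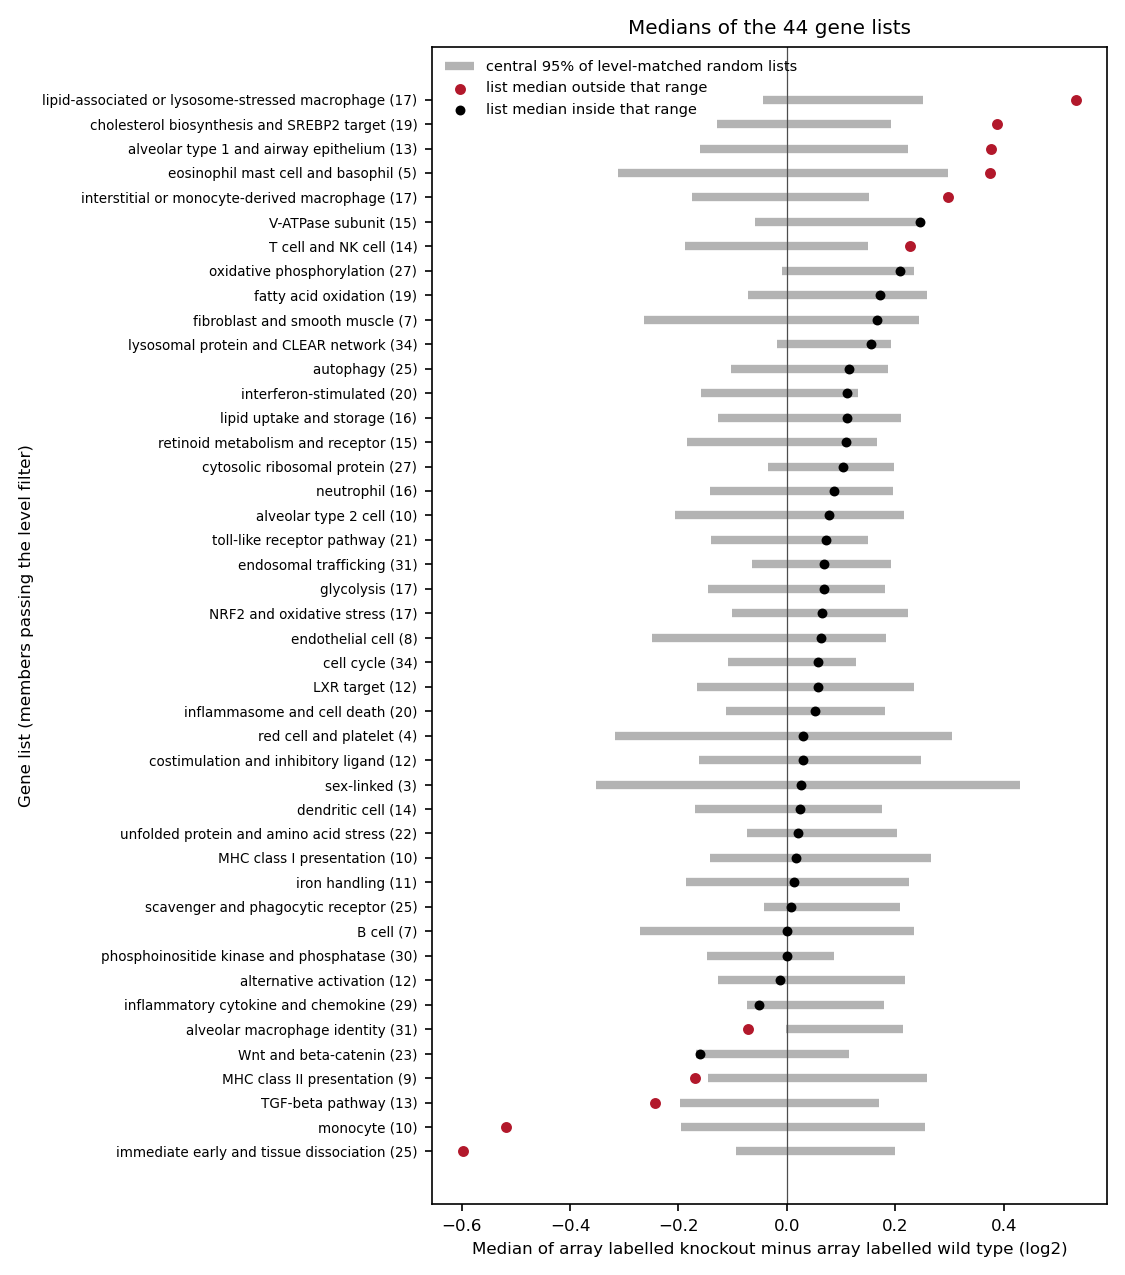
Median difference (labelled knockout minus labelled wild type, log2) of the members of each of the 44 gene lists that passed the filter (their number in brackets), as points, with the central 95% of 10000 level-matched random lists as grey bars. The lipid-associated list has the highest median, 0.53, and the immediate early list the lowest, -0.60.

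Of the 44 lists, 6 had a median above the central 95% of random lists and 5 had one below it. Genes of lipid-associated or lysosome-stressed macrophages had the highest median, 0.53, above all 10000 random lists. Of its 17 members that passed the filter, 15 were higher in the array labelled knockout, 5 by at least 2-fold, and none was 1.5-fold lower. Trem2, a lipid-sensing receptor, read 8.75 and 10.26 (2.86-fold). Gpnmb, a glycoprotein of lysosome-loaded macrophages, read 9.88 and 11.25 (2.58-fold). The lysosomal protease gene Ctsk read 10.88 and 12.20, and the tetraspanin gene Cd63 was 2.42-fold and the legumain gene Lgmn 2.07-fold higher. Cd9, of the same list, was lower (10.19 and 9.65). Of the list, 6 members also stand in another list, and the interstitial macrophage list, which shares Mmp12 and Apoe with it, had a median of 0.30.

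Cholesterol biosynthesis and SREBP2 target genes had a median of 0.39, above all random lists. Of 19 members, 17 were higher and 5 were at least 1.5-fold higher. Sc5d and Fdps, enzymes of the sterol and isoprenoid pathways, were 2.12-fold and 2.10-fold higher, Msmo1 was 1.70-fold higher and the sterol carrier gene Stard4 1.66-fold higher. Srebf2 itself read 6.41 and 6.23. LXR targets, which respond to sterol excess, had a median of 0.06, with Apoc1 at 0.62, Pltp at -0.60, Abca1 at -0.46 and Srebf1 at -0.43; it was 0.27 with the filter at the 75th percentile and -0.09 with no filter, inside the range in both.

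Lysosomal genes as a class lay inside the range of random lists. The lysosomal protein and CLEAR network list had a median of 0.16 over 34 members (percentile 91.2), with Cd63, Gla (1.74-fold), Naglu (1.62-fold) and Ctsl (1.51-fold) at least 1.5-fold higher and none 1.5-fold lower. The V-ATPase proton pump list had a median of 0.25 (percentile 97.3), with 13 of 15 subunits higher, and lay above the range under 2 of the 10 settings; Atp6v1c1 differed most, at 0.74. Autophagy genes had a median of 0.11 with Atg4a at 0.61. Endosomal trafficking genes had a median of 0.07, with Rab9 at 0.61 and Vps41 at 0.38. Phosphoinositide kinases and phosphatases had a median of 0.00 over 30 members, none of them 1.5-fold apart; Pip4k2a differed by -0.55 and Vac14, the scaffold of the PIKfyve complex, by -0.45.

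Immediate early and tissue dissociation genes had the lowest median, -0.60, below all 10000 random lists. Of 25 members, 23 were lower in the array labelled knockout and 14 were at least 1.5-fold lower. The transcription factor gene Egr2 read 9.49 and 8.31 (2.26-fold), the heat shock gene Hspa1a 10.58 and 9.43 (2.23-fold), Ier2 9.05 and 8.04 (2.01-fold) and Zfp36 10.60 and 9.68 (1.89-fold). Ier3 and Egr3 read higher, by 0.30 and 0.10. These genes respond to tissue handling as well as to stimuli, each genotype has 1 array, and the monocyte list was lower beside them, at -0.52. Inflammatory cytokine and chemokine genes had a median of -0.05 (percentile 5.03) but a mean of -0.27, and 5 of 29 members were at least 2-fold lower and none 2-fold higher. Those 5 were Tnf, Cxcl14, Cxcl3, Cxcl2 (2.24-fold) and Ccl2 (2.20-fold). The mean lay below all random lists, as did the median with the filter at the receptor-gene background (-0.32) or at the 75th percentile (-0.36).

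**Figure D3:**
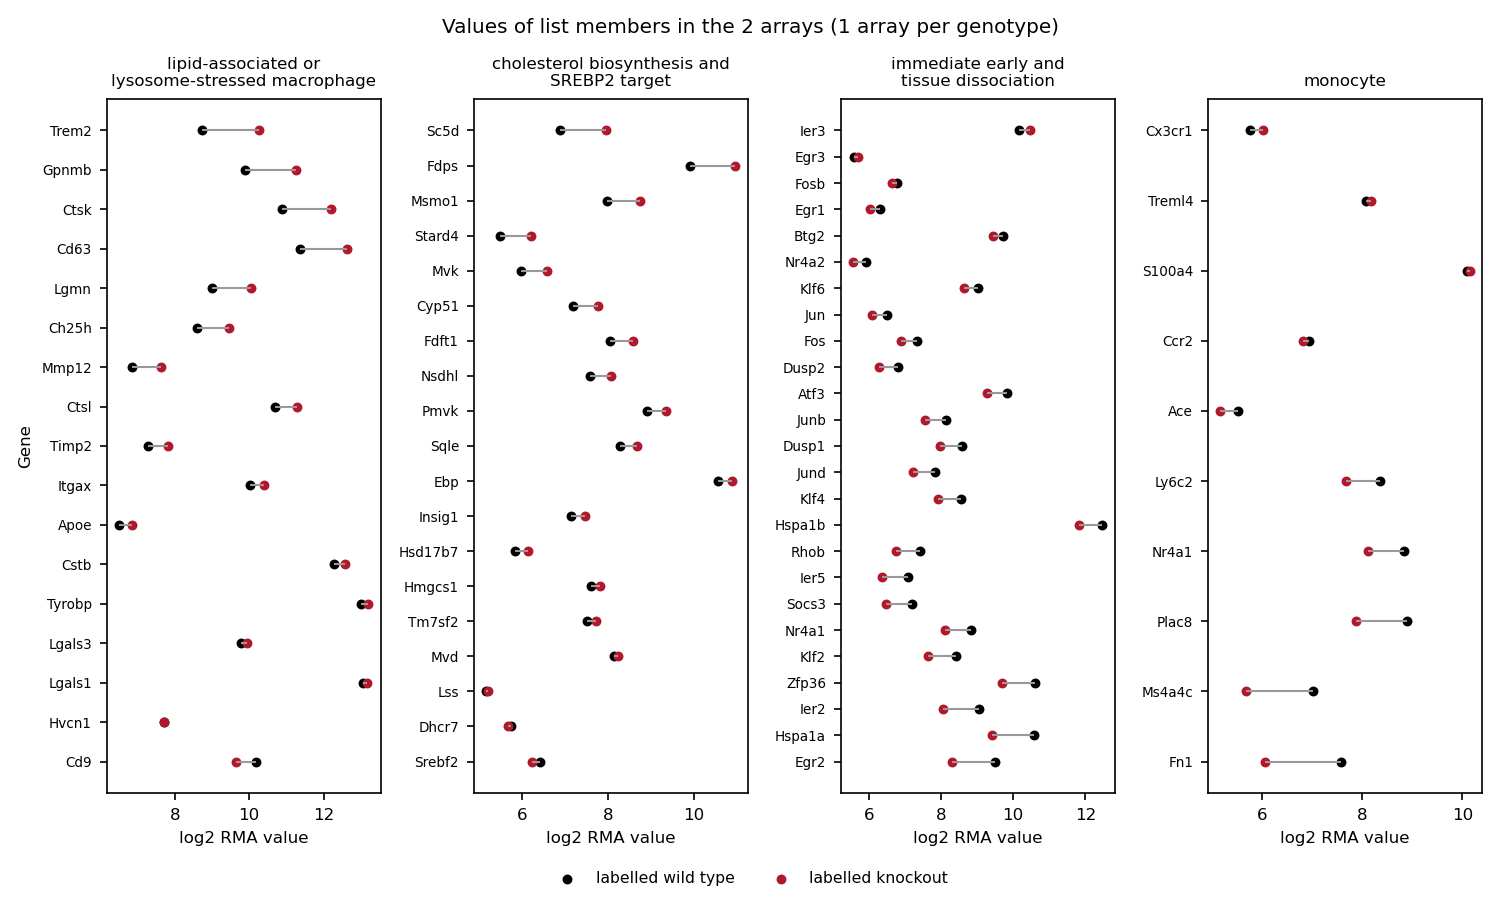
Values (log2 RMA) of each member that passed the filter in the array labelled wild type (black) and the array labelled knockout (red), for 4 lists; lines join the values of a gene. Trem2, Gpnmb, Ctsk, Cd63 and Lgmn lie at least 2-fold to the right in the array labelled knockout, and Egr2, Hspa1a, Ier2, Fn1, Ms4a4c and Plac8 at least 2-fold to the left.

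Alveolar macrophage identity genes were split in direction, and their median of -0.07 lay at percentile 0.13 of random lists of matched level. All 31 measured members passed the filter; 18 were lower and 13 higher, and their mean was 0.01, of the opposite sign and inside the range of means of random lists (percentile 4.44). The zinc transporter gene Slc39a2 was 3.18-fold higher and Ctsk differed by 1.32, while the keratin gene Krt79 was 1.97-fold lower. Siglecf, whose product was used for sorting, read 9.27 and 8.54, and Itgax, which encodes CD11c, read 10.03 and 10.39. Pparg, the transcription factor of alveolar macrophage differentiation, read 10.53 and 10.68.

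Monocyte genes had a median of -0.52, below all random lists. Of 10 members that passed the filter, 7 were lower, with Fn1, Ms4a4c and Plac8 (2.03-fold) at least 2-fold lower, Nr4a1 1.66-fold and Ly6c2 1.61-fold lower. Ccr2, the receptor of classical monocytes, read 6.93 and 6.80, and S100a4 read 10.09 and 10.14. Genes of interstitial or monocyte-derived macrophages had a median of 0.30 (percentile 99.99), with 14 of 17 higher; Ms4a7 was 2.38-fold, Tmem176a 2.13-fold, Mmp12 1.71-fold and Tmem176b 1.64-fold higher. Of the complement genes, C1qa differed by 0.04, C1qb by 0.64 and C1qc by 0.71, and Csf1r read 6.88 and 6.54. The interstitial median was 0.64 with the filter at the 75th percentile and 0.19 with the offset, above the range in both.

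Some markers of other lung cells lay above background in these sorted populations, and others did not. In the array labelled wild type, 16 of 16 neutrophil genes and 11 of 15 alveolar type 1 and airway epithelium genes reached that level. Only 4 of 14 endothelial, 5 of 13 fibroblast and smooth muscle, and 3 of 16 eosinophil, mast cell and basophil genes did. The alveolar type 1 and airway epithelium list had a median of 0.38 (percentile 99.95) with 10 of 13 members higher. Its airway secretory genes Bpifa1, Scgb3a1 (2.77-fold) and Scgb3a2 (1.99-fold) were higher, Scgb1a1, the club cell secretoglobin, read 12.26 and 12.39, and Epcam was lower. Alveolar type 2 genes had a median of 0.08, with Cxcl15 at 0.92, Lyz1 at 0.85, Sftpa1 at 0.84 and Napsa at -0.84; with the filter at the receptor-gene background (8 members) or at the 75th percentile (6 members) it was 0.51 or 0.81, above the range. T cell and NK cell genes had a median of 0.23 (percentile 99.6), with 10 of 14 higher; the granzyme gene Gzma was 2.21-fold (7.09 and 8.23) and Cd3d 1.72-fold higher. The T and NK cell median was 0.66 over 4 members with the filter at the 75th percentile and 0.13 with the offset, above the range in both. The eosinophil, mast cell and basophil list had a median of 0.37 (percentile 99.0) over only 5 members, led by Ear6 and by Prg2 (at background in the array labelled wild type, at least 1.31-fold higher), while Hdc differed by -0.65; with the filter at the 75th percentile only Ear6 is left, at 2.62. Neutrophil genes had a median of 0.09, with 8 higher and 8 lower, among them Camp at 1.09, Retnlg at 0.93, Ly6g at 0.78, Mmp8 at 0.70 and Csf3r at -0.64; with the filter at the 75th percentile it was 0.32, above the range. The endothelial median was 0.06 with Cav1 at least 2.17-fold higher, the fibroblast and smooth muscle median 0.17 with Inmt at 0.77, the dendritic cell median 0.02 with Ccr7 at 0.66, the B cell median 0.00 with Blk at -0.54, and the red cell and platelet median 0.03 over 4 members with Ppbp at 1.01. With the filter at the 75th percentile only Calcrl, at 0.93, was left of the endothelial list and the fibroblast median was 0.44, both inside the range, and only Ppbp was left of the red cell and platelet list, above the range; the endothelial mean, 0.26, also lay above it.

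TGF-beta pathway genes had a median of -0.24 (percentile 0.83), and 12 of 13 members were lower; with the filter at the 75th percentile, which kept 5 members, it lay inside the range (percentile 4.08). Tgfb2 was 1.87-fold, the integrin gene Itgav 1.62-fold, the receptor gene Tgfbr1 1.58-fold and Tgfb1 1.42-fold lower. MHC class II genes had a median of -0.17 (percentile 1.42), and none of the 9 members was 1.5-fold apart; H2-DMa differed by -0.38, H2-Ab1 by -0.29 and H2-Oa by 0.36. The mean of these 9 genes, -0.08, lay inside the range (percentile 7.74). Wnt and beta-catenin genes had a median of -0.16, inside the range, with Myc at -0.75, Axin1 (at background in the array labelled knockout) at least 1.62-fold lower and Ctnnb1, which encodes beta-catenin, at 0.61. Retinoid metabolism genes had a median of 0.11 (percentile 91.4), with Rdh11 at 0.78, the retinaldehyde dehydrogenase gene Aldh1a1 at 0.65 and the receptor gene Rara at -0.49; it lay above the range with no filter and with the filter at the 75th percentile, where it was 0.36.

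The remaining lists also lay inside the range of random lists on the values as deposited, though oxidative phosphorylation lay above it under 3 of the 10 settings, interferon-stimulated genes under 2 and NRF2 genes under 1. Among metabolic lists, oxidative phosphorylation genes had a median of 0.21 (percentile 93.3) with 26 of 27 higher and Ndufb3 at 0.67, fatty acid oxidation genes 0.17 with Echs1 at 0.60, glycolysis genes 0.07 with Pgam1 at 0.39, and lipid uptake and storage genes 0.11 with the scavenger receptor gene Msr1 3.39-fold higher. NRF2 and oxidative stress genes had a median of 0.06, with the cystine transporter gene Slc7a11 2.38-fold and Gsta3 at least 1.80-fold higher. Iron handling genes had a median of 0.01, unfolded protein and amino acid stress genes 0.02 with Asns at 0.95 and Ppp1r15a at -0.81, cell cycle genes 0.06 with Ndc80 at 0.70, and cytosolic ribosomal protein genes 0.10. Among immune lists, interferon-stimulated genes had a median of 0.11 with Cxcl10 at -0.81 and Ifit1 at 0.61. MHC class I genes had a median of 0.02 with H2-T23 at 0.92, and costimulation and inhibitory ligand genes 0.03 with Cd200 2.57-fold higher. Alternative activation genes had a median of -0.01 with Mgl2 at 0.86 and Arg1 at -0.25, scavenger and phagocytic receptor genes 0.01 with C3ar1 at least 1.78-fold higher, toll-like receptor pathway genes 0.07 with Tlr13 at 0.63, and inflammasome and cell death genes 0.05 with Nlrp3 at -0.87.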

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

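The tests in this part were chosen after the results were seen, except loess centring, an alternative fixed beforehand. Rows with no gene symbol or with several were left out of the comparison above. Among the 7291 of them that passed the filter, 136 were at least 2-fold higher and 207 at least 2-fold lower in the array labelled knockout. More were thus lower than higher, unlike the genes analysed above (116 higher and 42 lower). How many of these rows are under 2-fold when measured from background was not counted. Of the 1049 rows with several symbols, 7 were higher and 26 lower. Among those with large differences, 17549170 read 9.08 and 12.42, and 17284505, at background in the array labelled wild type, was higher by at least 1.64. In the other direction, 17467480 and 17467537 were at background in the array labelled knockout, with differences of -3.69 and -2.55 when measured from that level; their genes are not given in the sources used here.

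The first pattern is the Pikfyve row, which was not lower in the array labelled knockout. A signal that is background stays open, since the value in the array labelled wild type lay at percentile 96.3 of the receptor genes, so some silent genes read higher. By this row, exchanged labels cannot be told apart from correct ones, since it differed by only 1.05 local spreads. No other gene was used to check the labels. A deletion that leaves most probes of the row intact stays open, as does incomplete deletion by LysM-Cre, and neither was tested.

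The lower immediate early genes are the second pattern. Removing a level-dependent trend between the arrays by loess centring left the list median at -0.67, against -0.60 as deposited. Such a trend therefore does not account for the lower values. The median stayed below all random lists, but these are matched on level with or without centring, so that rank is no separate test. The handling of each preparation, such as time in collagenase or in the sorter, induces the same genes, and 23 of the 25 members were lower; with 1 array per genotype this cannot be told apart from an effect of genotype. Fewer monocytes stay open too, although the gate on Siglec-F and CD11c would remove them: the 9 monocyte markers outside the immediate early list had a median of -0.35 and 6 of them were lower, but S100a4, Treml4 and Cx3cr1 were not.

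The higher lipid-associated genes are the third pattern. After loess centring the list median was 0.47, against 0.53 as deposited, so a level-dependent trend accounts for little of it. It stayed above all random lists, though their match on level makes that rank no separate test. Interstitial macrophages stay open, although they lack Siglec-F and the gate would remove them: of their 15 markers outside the list, 12 were higher, with a median of 0.25, Ms4a7 at 1.25 and Tmem176a at 1.09, but C1qa at 0.04 and Csf1r at -0.35. A genotype effect stays open too, untested.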

How the results depend on the processing

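The count without predicted genes, small RNAs and receptor segments was added after the data were seen; the other alternatives were fixed beforehand. With 1 array per genotype no replicate could be left out. No paired analysis was possible because each group has 1 array. The filters and median centring cannot alter the value of a single gene, nor can the choice of row for a gene with 1 row. Of the alternatives that can, quantile normalisation, loess centring and the offset left Pikfyve higher, by 0.17 to 0.32. The numbers of genes at least 2-fold higher and lower, 116 and 42, were 557 and 333 at 1.5-fold, 37 and 4 at 3-fold, 175 and 117 with no filter on low values, and 62 and 18 with an offset of 32, which shrinks dim genes; they stayed within 1.5 times under the other alternatives. Under loess centring 104 of the 116 and 41 of the 42 were among the 107 and 49 called. Median centring and the threshold of 3 local spreads altered neither count, because the median difference was 0.00 and 3 local spreads stayed under 2-fold, so they test nothing. Without predicted genes, small RNAs and receptor segments the counts were 102 and 30. All 30 genes named by size kept their direction under those 3 alternatives, and 16 moved by more than the local spread, all with the offset. The number of lists above the range of random lists went from 6 to 10 with the filter at the 75th percentile. Of the 11 lists outside the range, 8 stayed outside it under all 10 settings, the eosinophil list with Ear6 alone at the 75th percentile. The 10 settings include the values as deposited and median centring, which could not move a list. MHC class II, TGF-beta and alveolar macrophage identity came inside the range under 1 setting each, and alveolar macrophage identity changed sign as a mean (0.0093). Of the 33 lists inside the range, cytokines lay below it under 3 settings, and above it lay oxidative phosphorylation under 3, V-ATPase, interferon, retinoid and type 2 cell genes under 2, and NRF2, endothelial, neutrophil, and red cell and platelet genes under 1. Of the other list medians, 379, among them those under median centring, stayed within 0.5 times the width of the random range and 16 did not. Under the filter at the 75th percentile these were LXR targets (0.27), T and NK cells (0.66), type 2 cells (0.81), endothelium (0.93), eosinophils (2.62, Ear6 alone), fibroblasts (0.44), cytokines (-0.36), interstitial macrophages (0.64), neutrophils (0.32), red cells and platelets (1.01) and retinoid genes (0.36). Under the receptor-gene background they were type 2 cells (0.51), eosinophils (0.71) and cytokines (-0.32), and as a mean NRF2 genes (0.26) and cytokines (-0.27). Fewer members pass the stricter filter, and the cause of the other shifts was not tested.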

Other observations

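The gene families and genes below were chosen after their values were seen, so a rank among random lists describes a family and is not a test. Genes with Rpl or Rps symbols, and Cd300, chemokine receptor and sialic acid-binding lectin genes, were also ranked and lay inside the range of random lists. Tetraspanins lay above it and guanylate-binding proteins below it. The Rpl and Rps set holds ribosomal protein genes, but also pseudogenes and genes of other proteins such as Rps6ka3. Each family median given kept its sign under median centring, quantile normalisation, loess centring and the offset. Small nucleolar RNA genes were lower in the array labelled knockout, with a median of -0.40 over 46 genes that passed the filter and 40 of them lower, below all 10000 level-matched random lists. Snord47 read 9.27 and 7.79, Snora41 read 8.41 and 7.21, and Snord52 differed by -1.20. Taf1d, a host gene of small nucleolar RNAs, read 8.35 and 7.35 over 11 averaged rows. MicroRNA genes had a median of -0.17 over 109 genes, 80 of them lower. The ribonucleases Ear6, Rnase2a and Rnase2b were 6.17-fold, at least 1.99-fold and 2.98-fold higher, though they share sequence. Of the 4 genes of Cd200 and its receptors that passed the filter, Cd200 and Cd200r2 (at background in the array labelled wild type) were at least 2-fold higher, Cd200r4 differed by 0.59 and Cd200r1 by -0.17. Of 12 glutathione S-transferase genes 8 were higher and 4 lower, with a median of 0.16 inside the range of random lists (percentile 92.9), and Gsta4 was 2.52-fold higher. Among cathepsin genes 10 of 12 were higher, with a median of 0.26 (percentile 98.6), led by Ctsk.

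Genes outside the naming rule with large positive differences included Hpgds, a prostaglandin D synthase, at 1.96, the phagocytic bridging protein gene Mfge8 at 1.95, the antimicrobial lectin gene Reg3g at 1.97, the transport motor gene Myo5a at 1.72 and Cd93 at 1.71. Siglece, an inhibitory lectin, was 2.03-fold lower. Of 10 immunoglobulin kappa variable segments 8 were higher, with a median of 0.78, above all random lists. At least 2-fold higher were 4 of them, among them Igkv8-30 (3.57, at background, and 8.63). Igkv4-91 and Igkv5-43 were lower, by -1.24 and -0.88, and Cd79b, a pan-B cell gene, read 7.60 and 7.63.

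A hypothesis tested on chromosomal neighbours was that DNA carried along with a modified locus from another strain might account for some differences; the test on Lyz2, the locus of the Cre driver, was set before its result was seen and that on Pikfyve after. Among 100 measured genes next to Lyz2 the standard deviation of differences was 0.30, at percentile 22.4 of 10483 windows of the same size. The spread of differences was thus not raised there. Passenger DNA that alters few or no genes would not raise it, so such DNA is not excluded. Among 100 measured genes next to Pikfyve it was 0.50, at percentile 97.0, with 4 genes at least 2-fold apart (Cxcr1, Fn1, Snora41 and Mreg, the last at background in the array labelled wild type and at least 1.21-fold higher) against a median of 1 per window. Without Cxcr1 it was 0.37, at percentile 77.9, while Fn1, Snora41 and Mreg remain. The other windows kept their largest gene in that ranking, so some fall in percentile was built in. Cxcr1 and Fn1, both among the named genes, lie near the targeted locus. Per the labels, both samples carry the same floxed Pikfyve alleles, so DNA carried along with those alleles would be expected in both. The DNA of that region was not examined, so whether it was the same in the 2 samples was not checked.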
